A study of Mus musculus with 12 samples.

How the data were processed

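The series comprises RNA sequencing of the olfactory mucosa from 12 male mice at postnatal day 30, strain label 129S6;C57BL/6J, 6 wildtype and 6 with a deletion of enhancer A. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a stranded, ribodepleted total RNA kit. The submitters' processing notes name STAR 2.6.0, DESeq2 without a version, and the build GRCm38.p6. The read counter, annotation release and strand setting are not given in the sources used here.

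The authors deposited 1 table with 46297 gene rows. Per the file headers, its 12 library columns and the base mean hold DESeq2-type normalized counts, a never negative signal equal to the read count of a gene divided by the size factor of the library. The authors' comparison gives a log2 fold change of wildtype over deletion with its standard error, a test statistic (a score) and p-values with adjusted p-values, blank for 25138 rows. From the values, the deposited log2 fold changes are shrunken towards 0. No row lacks reads in every library, all 12 library columns were matched to samples by their names, and 0 pairs of libraries were identical.

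Within a library, values are whole multiples of what 1 read is worth, so read numbers were recovered. At least 99.989% of values came out whole within 0.01. In the sixth deletion library 1 read is worth so nearly 1 that an automatic test could not separate this from rounding. Its values are multiples of a step just under 1, and its reads were recovered in the same way. The recovered reads sum to between 13011763 and 23039733 per library.

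The design written before the data were examined took raw counts as its first case and limma as its fallback for normalized values. Since the table holds normalized counts, the main test was limma 3.58.1 with a mean-variance trend on log2(value + 1), for genes with a mean value of at least 10 (19373 genes), with Benjamini-Hochberg adjustment at 5%. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes, and are deletion over wildtype. Count tests on recovered reads (edgeR 4.0.16 and DESeq2 1.42.0) served as alternatives. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. No covariate was used, and each animal gave 1 library.

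Class I receptors were Olfr33, Olfr64 to Olfr69, Olfr78 and Olfr543 to Olfr693 by symbol, and the remaining Olfr genes were class II (155 and 1237 rows). Olfr243 is counted in class II although it lies in the class I cluster, and Olfr693 in class I although it lies 4164 kb from the element. Gene positions came from GENCODE M21 (GRCm38), matched by gene identifier for 99.8% of rows. The build of the deletion coordinates is not named beside them, so they were read as GRCm38. Distance is the gap between the annotated gene and the deleted interval.

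Per library, the share of receptor reads from class I genes, the summed normalized counts of class I, class II and all receptors, and the mean log2 value of mature neuron markers were compared by two-sided exact permutation tests over 924 splits, adjusted over these 5 measures. The relation with distance was tested by permuting genes 100000 times. The 25 gene lists cover both receptor classes, cell types of the mucosa and tissues beside it, zones, receptor choice regulators, receptor signalling and axon guidance, immediate early genes, trace amine receptors, necklace neurons and non-receptor genes of the cluster. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry.

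Genes were named by a fixed rule: the 8 lower and 4 higher class I receptors with the smallest p past 5%; the 3 tested class I receptors nearest to the element on each side; the 3 class II receptors with the smallest p past 5% in each direction; the 5 other genes with the smallest p past 5% in each direction that have a mean log2 CPM of at least 0 and a symbol that is not a clone name; and the first member of each list, with Omp, Gap43, Krt5, Cyp2g1, Lhx2, Ldb1, Bcl11b and Taar2 named whatever their p. Only 2 class I receptors were higher, only 2 class II receptors were lower, and no gene met the rule for other genes. Trpc2, Taar1 and Ms4a4c were too low to test. Some genes that the rule would name are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

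The main and the edgeR tests were tested on simulated counts for the 19373 genes, drawn from the means and depths of these libraries with 200 genes changed, 50 at each of 4 sizes. For this comparison of 6 against 6, limma recovered 56% of 1.5-fold, 86% of 2-fold, 96% of 4-fold and 88% of 0.25-fold changes. There were 5 false among 168 calls. Each gene was drawn on its own, so differences that many genes of a library share are absent. Other groupings of the real libraries gave up to 75 calls, so the simulation may understate false calls in the real data.

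Alternatives fixed before the data were examined were DESeq2, edgeR with RLE size factors, limma-voom, scaling by library size alone, other low-value filters, pseudocounts of 0.5 and 5, a 1% threshold, a mature neuron covariate, a replicate block and leaving out each library. Alternatives added after seeing the data were edgeR with TMM, TMM scaling and the distance relation beyond 1 Mb. So were leaving out the 4 libraries with over 1% of reads in Gm10800, and that gene as a covariate. Leaving out wildtype library 1 with deletion library 3 was also added then. The edgeR test with TMM had been named beforehand as the main test for raw counts, but not as an alternative.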

Results

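The olfactory mucosa of 12 male mice at postnatal day 30 was profiled by sequencing of total RNA after ribosomal RNA depletion. The labels place 6 animals in a wildtype group and 6 in a group lacking enhancer A (eA), and describe the animals as age matched. The mucosa holds the olfactory sensory neurons, which carry odorant receptors at their surface, together with glands, supporting cells and the progenitors that replace the neurons. Mouse odorant receptors fall into class I, encoded in a cluster on chromosome 7, and class II, encoded at many sites in the genome. The series title names eA as an enhancer of class I receptors, so the comparison asks how the receptor genes and their neighbours were expressed without it. Between 13011763 and 23039733 reads per library fell on annotated genes, and 28832 to 42218 genes had at least 1 read.

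The deleted element spans 912 bp on chromosome 7, from 102509701 to 102510612, read as coordinates of GRCm38, the build in the submitters' processing notes. It overlaps 0 annotated features in GENCODE M21. The nearest gene before it is the class I receptor gene Olfr545 (102491466 to 102499573), 10128 bp away, and the nearest after it is the clone-named gene RP23-61O11.12 (102520346 to 102521009), 9734 bp away. No gene count therefore measures the element itself. The labels do not say whether the animals carried the deletion on both chromosomes.

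Class I receptor genes were broadly lower in the deletion. Of the 116 that could be tested, 63 were lower and 2 were higher at an adjusted p under 5% over all genes (limma), and 51 did not pass. On the side before the element, the nearest receptor genes lost most of their signal: Olfr544, 21.4 kb away, fell from 126 ± 25.6 to 9.66 ± 4.03 normalized counts (SD, n = 6 each), and Olfr543, 28.02 kb away, fell from 86.4 ± 8.80 to 8.18 ± 3.51. Some distant members fell as far, among them Olfr657 at 2114 kb, which went from 67.1 ± 9.87 to 1.74 ± 1.58, a 38.5-fold difference of the means. A pair of receptor genes rose: Olfr653 from 532 ± 32.2 to 1101 ± 213 and Olfr65 from 211 ± 23.5 to 393 ± 67.3.

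The 8 lower class I genes with the smallest p were lower in 6 of 6 deletion libraries than the wildtype mean. Their selection by p in these same libraries makes this likely, so it is no separate support. Olfr582 (ENSMUSG00000073961.4, 103038024 to 103044040) had a log2 change of -4.38 ± 0.27 (SE), from 83.3 ± 18.5 to 3.19 ± 1.40, with an adjusted p of 3.4e-07 by limma. Olfr591 fell 4.15-fold, from 266 ± 33.9 to 64.2 ± 11.3. Olfr569 and Olfr639 fell 4.81-fold and 4.82-fold, although they lie 373 kb and 1496 kb from the element. Olfr618 fell 9.63-fold, from 56.9 ± 8.84 to 5.91 ± 1.32. Olfr544 and Olfr543 had log2 changes of -3.64 ± 0.25 and -3.34 ± 0.24, and Olfr657 one of -4.81 ± 0.34. Both higher genes, also picked by p, were above the wildtype mean in 6 of 6 deletion libraries. The log2 change was 1.03 ± 0.10 for Olfr653, with an adjusted p of 2.61e-05, and 0.89 ± 0.11 for Olfr65, with an adjusted p of 0.000342.

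Among the 63 lower genes the log2 change was below -3 for 12, between -3 and -2 for 14, between -2 and -1 for 27 and closer to 0 for 10, with a median of -1.72. Over all 116 class I genes tested the median was -0.92, and 102 had a negative and 14 a positive estimate, while the median over all 19373 genes was 0.0087. Adjusted over the list alone, 83 class I genes were lower and 7 were higher. The 5 that were higher only by that adjustment were Olfr594 (log2 change 0.59), Olfr667 (0.48), Olfr693 (0.25), Olfr609 (0.26) and Olfr587-ps1 (0.40), named after their values were seen. A further 39 class I genes had mean values too low to test. Receptor genes have close paralogs and the counting settings are not given in the sources used here, so the value of a single receptor gene is less certain than that of the class.

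**Figure D1:**
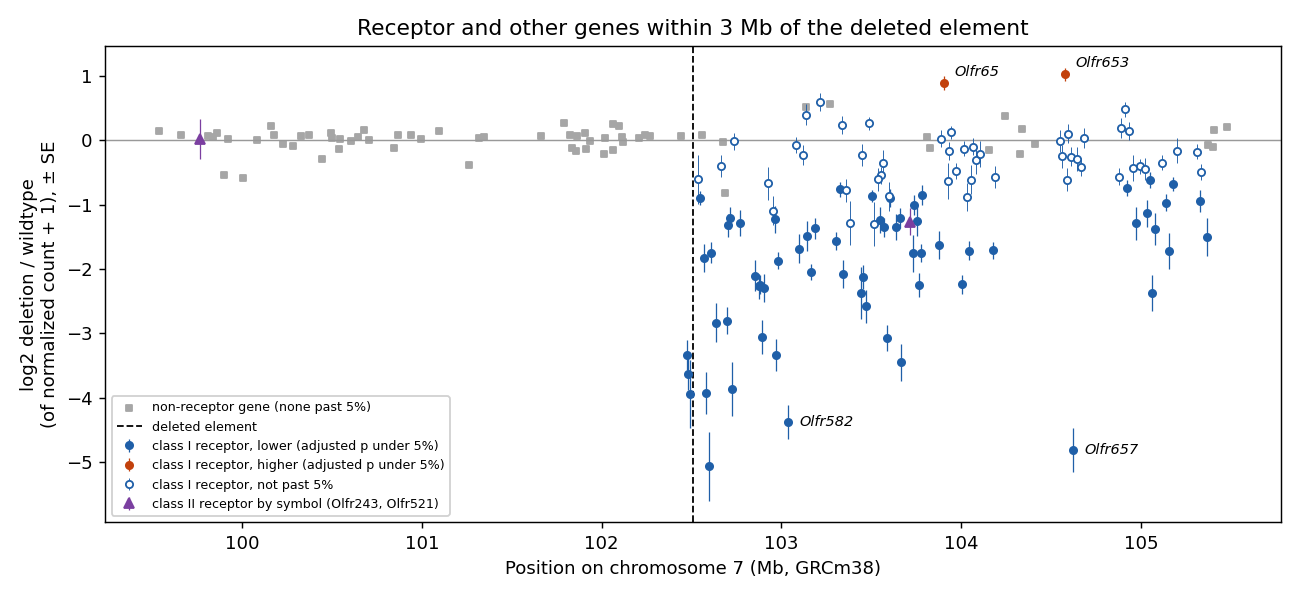
Change of each tested gene within 3 Mb of the element, plotted by its position on chromosome 7 (Mb) against the log2 of deletion over wildtype, with standard errors for receptor genes. Class I receptor genes lie mostly below 0, Olfr653 and Olfr65 lie above it at 1.03 and 0.89, and 0 of the 68 non-receptor genes pass the 5% threshold.

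**Figure D2:**
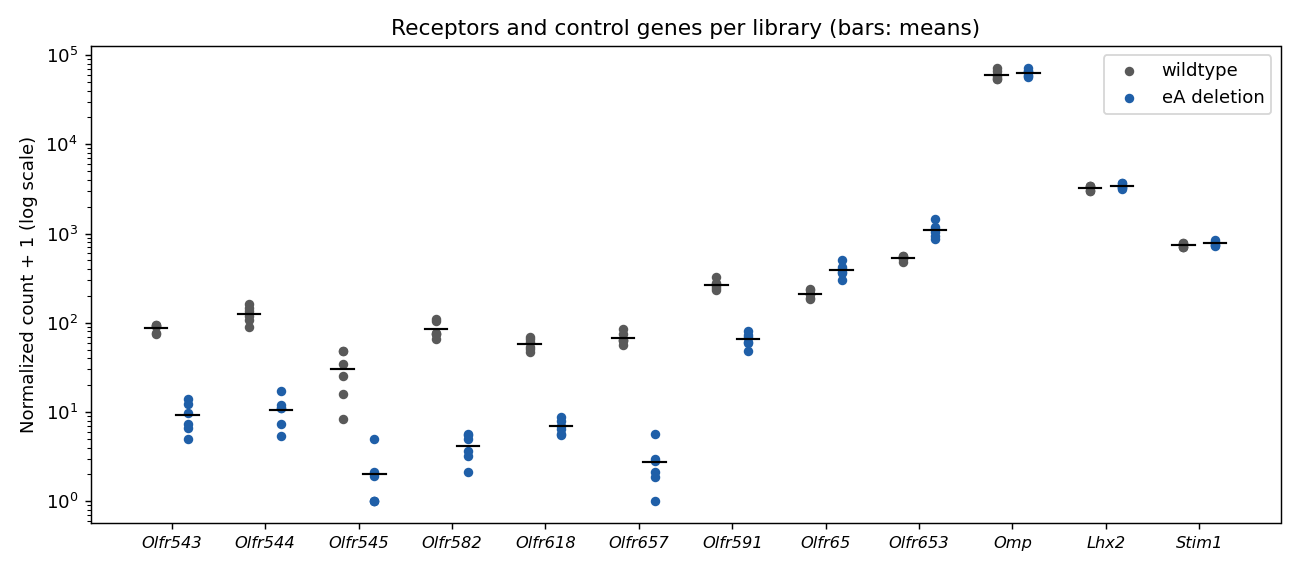
Normalized counts plus 1 of 9 class I receptor genes and 3 other genes in each of the 12 libraries, on a log scale, with a bar at each group's mean. The 7 receptor genes on the left are lower in the deletion, Olfr65 and Olfr653 are higher, and Omp, Lhx2 and Stim1 did not pass the test.

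The receptor genes around the element were compared by position to ask whether distance from it mattered. On the side before the element, Olfr545, Olfr544 and Olfr543 were all lower. Olfr545 went from 29.0 ± 16.6 to 1.01 ± 1.55, a log2 change of -3.94 ± 0.53. On the side after it, Olfr549 (39.3 kb) and Olfr550 (60.8 kb) fell 1.85-fold and 3.61-fold, while Olfr547 (24.1 kb) did not pass the test, with 14.97 ± 6.13 against 9.44 ± 4.80 and an adjusted p of 0.78. Olfr78, a class I receptor also expressed outside the nose, lies 228 kb away and had 110 ± 8.68 normalized counts in wildtype and 110.0 ± 22.6 in the deletion. It was chosen after its values were seen, and its estimate changed sign between settings.

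Within 0.5 Mb of the element 22 of 27 class I genes were lower, with a median log2 change of -2.10. The count was 12 of 21 from 0.5 to 1 Mb (median -1.29), 15 of 26 from 1 to 1.5 Mb (median -1.11) and 14 of 41 from 1.5 to 3 Mb (median -0.45). Both higher genes lie beyond 1 Mb. Across the 115 genes within 3 Mb, the log2 change rose with distance (Spearman's rho 0.43, Pearson's r 0.42, permutation p 1e-05, the smallest that 100000 resamples can give). These are genes of the same libraries and not independent replicates. Among the 67 genes over 1 Mb away the relation did not pass the test (rho 0.21, permutation p 0.0816), a subset chosen after seeing the data. The same rank correlation was 0.45 in the 8 libraries with at most 1% of reads in the satellite gene Gm10800 and 0.41 in the other 4, which are described further on.

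As a group, class I genes supplied a smaller part of all receptor reads without the element. Their share was 10.5% ± 0.97 (SD, n = 6) in wildtype and 6.82% ± 0.72 in the deletion, a difference of -3.66 percentage points (two-sided exact permutation p 0.002165, the smallest 924 splits allow, and 0.0054 after adjustment over 5 measures). The groups did not overlap. The lowest wildtype library was at 9.04% (Wilson 95% interval 8.89 to 9.20) and the highest deletion library at 7.73% (7.59 to 7.87), intervals that cover counting error only. The summed class I signal was 14006 ± 905 normalized counts in wildtype and 9420 ± 1208 in the deletion, a change of -32.7% (exact permutation p 0.002165, adjusted 0.0054). Olfr653 alone went from 3.80% to 11.7% of the class I signal.

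**Figure D3:**
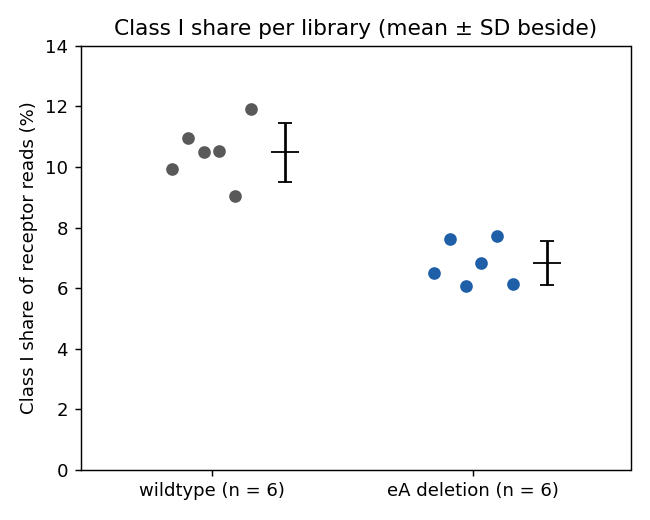
Share of odorant receptor reads from class I genes, in percent, for each of the 6 wildtype and 6 deletion libraries, with the mean ± SD beside the points. The wildtype libraries lie between 9.04% and 11.9% and the deletion libraries between 6.06% and 7.73%.

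The share was also lower within each set of libraries defined by Gm10800. In the 8 libraries with at most 1% of their reads in it, the share was 10.4% ± 1.21 in 4 wildtype and 7.18% ± 0.60 in 4 deletion libraries (exact permutation p 0.0286, the smallest possible there). In the other 4 it was 10.7% in 2 wildtype and 6.10% in 2 deletion libraries, where the smallest possible exact p is 0.333. These sets were defined after seeing the data.

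Few class II receptors passed the test as single genes. Of 952 tested, 2 were lower and 4 were higher (limma, adjusted p under 5%), and adjusted over the list alone 3 were lower and 6 higher. The lower ones were Olfr243 (47.8 ± 8.53 to 19.7 ± 6.01) and Olfr304 (40.2 ± 16.6 to 7.86 ± 3.60). Olfr243 lies inside the class I cluster, at 103714671 to 103721166, and was placed in class II by its symbol alone. The higher ones were Olfr1370 on chromosome 13 (261 ± 48.2 to 396 ± 34.8) and, 15812 to 15981 kb from the element on chromosome 7, Olfr297, Olfr292 and Olfr295, the last named after its values were seen. Olfr297 had 53.3 ± 72.9 in wildtype, where library 1 alone stood at 201, and 193 ± 44.4 in the deletion. Olfr304 lies in the same stretch, 16.1 Mb away.

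The count of 6 class II genes was less stable than that of class I. The edgeR quasi-likelihood test on recovered reads gave 3. Leaving out any 1 of wildtype libraries 2 to 6 or deletion library 6 gave 2, any 1 of deletion libraries 1, 2, 4 or 5 gave 3, and the 8 libraries with little Gm10800 signal gave 1. The count stayed at 6 without deletion library 3. It rose to 8 without wildtype library 1, and to 9 without both of these libraries. Over the class, 607 genes had a positive and 345 a negative estimate, with a median log2 change of 0.078. At an unadjusted p under 0.05 stood 131 of the 952 class II genes (limma), above the 5% expected of unchanged independent genes. Genes of the same libraries are not independent. The fry test for changes in either direction gave p 0.0082, and 0.102 after adjustment over the lists. The summed class II signal was 120153 ± 9191 in wildtype and 128563 ± 5122 in the deletion, which did not pass after adjustment (7.0% higher, exact permutation p 0.039, adjusted 0.0649). Without wildtype library 6, which had the lowest sum, it was 3.88% higher (exact permutation p 0.0823). All receptors together summed to 134159 ± 9255 and 137983 ± 5827 (exact permutation p 0.506).

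Genes other than receptors around the element did not pass the test. Of 68 tested within 3 Mb, 0 were called by limma, with 2 at an unadjusted p under 0.05. The edgeR quasi-likelihood test called 0 of 69, with 3 unadjusted, and DESeq2, run without the low-value filter, called 0 of 174, with 4. Stim1, a calcium sensor of the endoplasmic reticulum whose gene ends 72.4 kb before the element, had 740 ± 39.1 normalized counts in wildtype and 773 ± 43.7 in the deletion. Atg16l2, named after its values were seen, was called without deletion library 4 (log2 change -0.45, adjusted p 0.0092), against -0.38 and 0.18 with all libraries.

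Over all 19373 genes tested, 72 passed, 66 lower and 6 higher. Besides the 71 receptor genes, the only call was RP23-474B13.5, an unnamed transcript 9801 kb before the element on chromosome 7 (92706773 to 92708279), which fell from 30.9 ± 7.32 to 3.48 ± 1.32. It was named after its values were seen. Of the 72, only Olfr1370 lies outside chromosome 7.

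Markers of the cell types of the mucosa did not pass the test. Omp, a protein of mature olfactory neurons, had a log2 change of 0.065 ± 0.098, and Gap43, a growth protein of immature neurons, one of -0.0078 ± 0.11. Their estimates changed sign between settings. The basal cell keratin Krt5 had 0.092 ± 0.13 and Cyp2g1, an enzyme of supporting cells, 0.11 ± 0.09. Changes were 0.071 ± 0.098 for Sox9 of gland cells, -0.044 ± 0.082 for Ascl3 of microvillar cells and 0.079 ± 0.079 for Foxj1 of ciliated cells. Sox9 and Foxj1 do not stand for their lists: of 9 gland genes 5 were lower and 4 higher, from -1.52 for Obp1b to 1.65 for Bpifb9a, both named after their values were seen, and of 9 ciliated cell genes 8 were lower, 3 at an unadjusted p under 0.05. Log2 changes were -0.55 ± 0.24 for the haemoglobin gene Hba-a1, -0.20 ± 0.097 for the leukocyte gene Ptprc and 0.15 ± 0.14 for the endothelial gene Pecam1. The bone gene Bglap had 0.26 ± 0.27 and the muscle gene Acta1 -0.051 ± 0.36. Ptprc and Ascl3 went against most of their lists. Of 12 immune genes 10 were higher and 2 lower, and of 7 microvillar genes 5 were higher and 2 lower. The mean log2 value of 16 mature neuron markers was 13.15 ± 0.13 in wildtype and 13.21 ± 0.07 in the deletion (exact permutation p 0.299).

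Genes with known roles in receptor choice, zones and axon guidance did not pass in limma over all genes either, without covariates. Lhx2 and Ldb1, a transcription factor and its partner at receptor enhancers, had log2 changes of 0.071 ± 0.057 and 0.023 ± 0.053. Bcl11b, a transcription factor with a known role in the choice between receptor classes, had 0.17 ± 0.082. Nqo1, a marker of the dorsal zone, had -0.22 ± 0.105, Ncam2 of the ventral zone 0.012 ± 0.064, the axon sorting gene Kirrel2 -0.20 ± 0.21, the immediate early gene Fos 0.014 ± 0.35 and the trace amine receptor gene Taar2 -0.14 ± 0.14. Adjusted over the list alone, 3 members of these lists passed, named after their values were seen: Robo2 of the dorsal zone (-0.19), Nfix of the ventral zone (0.32) and Car2 of the necklace neurons (0.19). Over all genes Nfix had an adjusted p of 0.524, but passed with the mature neuron covariate (0.42, adjusted p 0.0395) and with the Gm10800 covariate (0.47, adjusted p 0.0457).

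Of 25 gene lists fixed before the data were examined, 7 passed camera with a preset correlation of 0.01. Class I receptors were lower (adjusted p 2.39e-106) and held with an estimated correlation (adjusted p = 0.000621) and in fry (adjusted p = 3.83e-06). Class II receptors, mature neurons, neuronal progenitors and endothelium were shifted upwards, with adjusted p of 0.0111, 0.0458, 0.0416 and 0.0458. Respiratory ciliated cells and erythroid cells were shifted downwards, each with 0.0458. With an estimated correlation none of these 6 held (adjusted p = 0.668 for mature neurons and 0.569 for each of the others), and no member of the 5 marker lists passed on its own. The other 18 lists did not pass, with adjusted p from 0.0722 to 0.894. They were immature neurons, horizontal basal cells, supporting cells, Bowman's gland, microvillar cells, ensheathing glia, vomeronasal neurons, immune cells, bone and cartilage, skeletal muscle, dorsal zone, ventral zone, receptor choice regulators, receptor signalling and axon guidance, immediate early genes, trace amine receptors, necklace neurons, and non-receptor genes of the class I cluster.

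Libraries differed in their signal of a satellite gene. Gm10800, a predicted gene in a satellite region of chromosome 2 (98666547 to 98667301), took 7.80% and 7.01% of reads in wildtype libraries 2 and 3 and 4.50% and 2.78% in deletion libraries 3 and 6. The other wildtype libraries held 0.079% to 0.885% and the other deletion libraries 0.0013% to 0.010%. The 4 libraries with over 1% also had the most genes detected. Without them, class I had 43 lower and 3 higher genes among 60 calls, and 12 of the 13 non-receptor calls were predicted genes with Gm names, Gm10800 among them, all lower in the deletion. Gm10800 itself had a log2 change of -6.74 in those 8 libraries (limma, adjusted p 0.00174), and of -4.86 ± 1.96 with an adjusted p of 0.726 in all 12. With the log2 value of Gm10800 as a covariate, class I had 54 lower and 2 higher genes.

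The authors' deposited table holds 91 genes with an adjusted p under 0.05, 80 higher in wildtype and 11 higher in the deletion. Class I receptors make up 72 of these in the authors' deposited table, 69 of them higher in wildtype, and 7 are class II receptors. The remaining 12 genes of the authors' deposited table include 4 on chromosome 7 and Robo2 (0.18, log2 of wildtype over deletion, adjusted p 0.0375). Fold changes in the authors' deposited table are shrunken, with Olfr591 at 1.26 and Olfr653 at -0.75 (log2 of wildtype over deletion).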

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

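The tests on chromosome 7 in this part were chosen after the results were seen. Each group of 6 libraries was examined for a library whose gap to its nearest neighbour exceeded 0.625 of the group's range, which chance gives in about 1 of 20 groups. Of 106 groups, 13 held such a library. The groups include genes named after their values were seen, among them Hddc3, Pgpep1l, Olfr293 and Olfr295. The 13 therefore cannot be set against that rate.

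In wildtype library 1, 7 genes of chromosome 7 stood apart from the other wildtype libraries and near the deletion group. Olfr304 was at 8.32 normalized counts against 37.6 to 53.9 in the others, and Hddc3, a nucleotide phosphohydrolase gene, at 104.5 against 255 to 338. Olfr297 was at 201 against 10.6 to 39.0, Olfr292 at 62.0 against 19.5 to 26.9, Olfr295 at 140 against 27.5 to 68.7, and Olfr293 at 178 against 10.8 to 24.2. Pgpep1l, a peptidase gene, was at 104.5 against 16.9 to 28.8. In deletion library 3, Hddc3 stood at 218 against 91.1 to 108 in the other deletion libraries, on the side of the wildtype group. Hddc3, Pgpep1l, Olfr293 and Olfr295 were named after their values were seen.

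These genes belong to a wider pattern. On chromosome 7 beyond 3 Mb from the element, 49 of 1415 genes (3.46%) had an unadjusted p under 0.01, 22 lower and 27 higher, against 174 of 17752 (0.98%) on other chromosomes (odds ratio 3.62, Fisher's exact p 3.28e-12, across genes). From 80 to 90 Mb it was 15 of 102 and to 100 Mb 6 of 71, but past the far edge of the 3 Mb window it was 0 of 94 to 110 Mb, 0 of 78 to 120 Mb, 0 of 158 to 130 Mb, 0 of 58 to 140 Mb and 4 of 122 to 150 Mb. Within the window, which these bins leave out, it was 1 of 68 non-receptor genes. Each library was then placed, from the other 11, on a scale where 0 is the wildtype and 1 the deletion level. At 50 to 90 Mb wildtype library 1 stood at 1.02, the other wildtype libraries between -0.31 and -0.12 and deletion library 3 at 0.46, while the class I receptors of wildtype library 1 stood at 0.0054. A wildtype library at the deletion level is not what action of the deletion over this distance would give. This rests on single libraries, so such action stays open. On other chromosomes, for comparison, the scale did not part the groups (wildtype 0.18 to 0.96, deletion 0.21 to 0.64). Strain variants linked to the deletion are a hypothesis: wildtype library 1 may share alleles of the deletion animals at 50 to 90 Mb, but the counts up to 140 Mb go against a differing segment that extends past the window on the far side, and no genotype was analysed here.

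The other flags concern single values. The class II sum of wildtype library 6 was 102120 against 119104 to 125985, and its sum over all receptors 115933 against 133064 to 139877. The sum over all receptors of deletion library 2 was 149039 against 132221 to 138388. Olfr549 in wildtype library 4 was at 267 against 231 to 239. Olfr545 in deletion library 6 was at 3.99 against 0 to 1.14.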

How the results depend on the processing

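The alternatives that leave out libraries for Gm10800 or chromosome 7, or use Gm10800 as a covariate, were chosen after seeing the data. So were TMM scaling and the distance relation beyond 1 Mb. The edgeR fit with TMM, which the design named for raw counts, was added as an alternative after seeing the data. Across all settings the number of called genes lay between 59 and 88 and that of class I genes between 46 and 72. Both stayed within 1.5 times the main counts of 72 and 65. The class I share stayed lower, by -3.95 to -3.38 percentage points with 1 library left out. No named class I receptor lost its call. The calls of Olfr243, Olfr304, Olfr1370, Olfr297, Olfr292 and Olfr295 were lost in 68 settings counted over genes.

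For class II receptors, with 6 genes called, edgeR gave 3 with TMM and 3 with RLE size factors, the mature neuron covariate gave 2, the 1% threshold 1, the 8 libraries with little Gm10800 signal 1 and the Gm10800 covariate 0; leaving out 1 library gave 2 to 8. Non-receptor genes within 3 Mb went from 0 to 1 (Atg16l2) with the Gm10800 covariate, and lay between 0 and 1 with 1 library left out. An estimated correlation left 1 list of 7. Beyond 1 Mb rho was 0.21, with fewer genes. For the rest the cause was not tested.

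No label says that the replicate numbers pair the libraries. Correlations between same-numbered libraries ran from -0.15 to 0.36, and libraries were not all best with their own number. These correlations do not settle whether the animals were paired. With the number as a replicate block 71 genes were called, 57 class I, 4 class II and 10 others. Among the others were the secreted protein genes Obp1a (-1.35, adjusted p 0.00237), Obp1b (-1.52, 0.00154) and Mup4 (-2.01, 0.00119), named after their values were seen, with adjusted p of 0.638, 0.702 and 0.599 without the block. With the block the Bowman's gland list also passed camera at the preset correlation, shifted downwards (adjusted p 0.048). Without the block its camera adjusted p was 0.282.

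Some estimates of uncalled genes changed sign, and the cause was not tested. With the mature neuron covariate Omp was at -0.032, Acta1 0.11 and Ncam2 -0.0066; with the Gm10800 covariate Omp was at -0.025, Acta1 0.45 and Ncam2 -0.037. Without the 4 libraries with over 1% of Gm10800 reads, Krt5 was at -0.024, Ascl3 0.018, Bglap -0.046 and Olfr78 0.015. Without wildtype library 1 and deletion library 3, Gap43 was at 0.067, Fos -0.10 and Olfr78 0.042. Gap43 was at 0.0063 with library size alone, Acta1 at 0.0072 with DESeq2 and 0.0020 with edgeR, and Olfr78 at 0.0012 with DESeq2. With 1 library left out the ranges were -0.078 to 0.067 for Gap43, -0.25 to 0.21 for Acta1, -0.021 to 0.048 for Ncam2, -0.18 to 0.29 for Fos, -0.0028 to 0.048 for Ldb1 and -0.10 to 0.058 for Olfr78. The low-value filter left out 39 class I genes; without it all 155 were tested and 70 called, 68 of them lower.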

Other observations

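Of the tests in this part, only the relation of reads with exonic length was written down before its result was seen. Among 99 other groupings of the 12 libraries into 6 and 6, the one with the most calls (75 genes) set wildtype libraries 1 to 4 and deletion libraries 1 and 2 against the rest, so it was not balanced by genotype. Its calls included Obp2a, Obp2b, Lcn3 and Lcn4, with log2 differences of -2.89, -4.24, -4.38 and -4.76 (the rest over these 6), and Postn, Lox, Col3a1, Spp1 and Dmp1, with 0.66, 0.68, 0.61, 1.48 and 1.43. These genes were picked after their values were seen from a grouping picked for its number of calls, and no enrichment was tested. No class I receptor was among the 75.

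Class I receptors in the same part of the cluster could move in opposite directions. The pairs given here were picked after their values were seen, and other receptor genes lie between their members. Olfr653 ends at 104584117 and rose 2.07-fold, while Olfr657 begins at 104624794 and fell 38.5-fold. Olfr65, 1393 kb from the element, rose 1.86-fold, and Olfr639, 1496 kb away, fell 4.82-fold. In the alternative without wildtype library 1, 11 non-receptor genes were called, and 10 of them lie on chromosome 7, among them Hddc3, Sh3gl3 and Pgpep1l.

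Other groupings of the libraries were used to ask what chance gives. The 72 genes called were matched or exceeded in 2 of 100 groupings, the real one included, with 75 as the highest other. For class I receptors it was 1 of 100, with 65 genes against 1 as the highest other, and for class II 1 of 100, with 6 against 2. Since the real grouping is included, 1 of 100 is the smallest share possible. The class I count lay far beyond the other groupings drawn, so chance is an unlikely source of it. For class II chance is not excluded. Of its 6 genes, Olfr297, Olfr292, Olfr295 and Olfr304 lie in the same stretch of chromosome 7. Olfr243 lies in the class I cluster, so the 6 may not be independent. The class II count fell to 2, the highest other, when any 1 of 6 libraries was left out. It fell to 1 without the 4 libraries high in Gm10800 and to 0 with Gm10800 as a covariate. Without wildtype library 1 it rose to 8, so it is not secure. The total of 72 lies within what regrouping gave. For non-receptor genes near the element the count of 0 was matched in 100 of 100. Any grouping must match a count of 0, so this comparison could not decide anything. The highest other was also 0. For gene lists, 34 of 100 groupings gave 7 or more, up to 12, so chance cannot be excluded for the number of lists.

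The lower class I signal was weighed against 3 technical explanations. Fewer mature neurons of all kinds would lower class II receptors as well, and the median class II change was 0.078. That value cannot exclude fewer neurons expressing class I receptors, which need not lower class II receptors. RNA of the whole mucosa cannot part fewer such neurons from less transcript in each. Genomic DNA in some libraries is argued against as the whole cause by the median class I change of -1.03 with Gm10800 as a covariate, against -0.92 without. Leaving out the 4 libraries high in Gm10800 decides nothing, since the gene still differs between the groups in the other 8. Deletion libraries 3 and 6, with 4.50% and 2.78% of reads in Gm10800, had class I shares of 6.06% and 6.15%. Wildtype libraries 1, 4, 5 and 6 held only 0.079% to 0.885%, but had shares of 9.04% to 11.9%. That order argues against genomic DNA as the source of the lower share in these libraries. Strain variants linked to the deletion cannot be told apart from it: between 90 Mb and the 3 Mb window the scale of 0 for wildtype and 1 for deletion rests on 3 to 5 genes and barely separates the groups, with wildtype library 6 at 0.498 and deletion libraries 1 and 2 at 0.504 and 0.645. Action of the deleted element on the cluster remains a hypothesis beside them. Of 68 non-receptor genes within 3 Mb, 0 were called and 1 (1.47%) had an unadjusted p under 0.01 (limma). That rate was 0.98% on other chromosomes and 3.46% on chromosome 7 beyond 3 Mb. From 90 to 100 Mb it was 6 of 71 genes, and the called transcript RP23-474B13.5 lies there. The count within 3 Mb is too small to decide on a differing segment around the element. Variants in the receptor genes alone were not tested.

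The 4 libraries with over 1% of reads in Gm10800 had at least 36565 genes detected, against at most 33895 in the other 8. Deeper sequencing is argued against, since they held 0.809 times the reads of the others on average. Genomic DNA is a candidate explanation: over 14782 genes nearly silent in the other 8, the signal in these 4 rose with exonic length (Spearman's rho 0.60). No biological explanation was tested.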
